A study of Rattus norvegicus with 2 samples.

How the data were processed

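MicroRNA levels were measured in 2 tissues of the male Sprague-Dawley rat on 2-colour arrays of the miRCURY LNA type, whose capture probes carry locked nucleic acids, modified nucleotides that bind short RNAs tightly. Per the labels' protocols, the fracture callus or the nonunion tissue of 5 animals was pooled within each group, total RNA was isolated from the pool, and 1000 ng was labelled. The sample was labelled with Hy3, read in the green channel, and a common reference with Hy5, read in the red channel, in the same orientation on both arrays. The labels describe the reference as a mix of the samples in equal volumes.

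Per the file headers, the arrays were scanned in 2 channels and quantified with Agilent Feature Extraction 10.7.3.1 under a miRCURY protocol. The deposited intensity columns used here are the median pixel brightness of each spot and of its local background in each channel; mean spot signals are not among the columns used here. The deposited processed signals, also an intensity, were background-subtracted and dye-normalized by the authors' scanner software, whose statistics block in the file lists spatial detrending and a lowess dye fit. The deposited LogRatio column holds log10 of red over green processed signal. Other deposited columns are flags and scores of 0 or 1 for spots well above background, saturated or outlying. The authors also deposited a table of 2680 probe IDs with 1 value per array, whose scale and direction the table does not state. It was set against the scanner values. Over probes with a processed Hy3 signal of at least 64, 98.6% of its values on each array lay within 0.01 of the mean log2 of green over red processed signal, with slopes of 1.00 and 0.999, so its values were read as log2 of sample over reference. For these probes the deposited log2 values thus match the scanner software's dye-normalized signals averaged over spots. Its column medians were -0.049 for standard and -0.041 for nonunion, so that it is close to centred on 0. Dimmer probes differed from that mean more (32.8% and 30.8% within 0.01), and how the authors treated them is not given in the sources used here.

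Probes carry numeric IDs, and 0 spots on the arrays have a systematic name. No table pairing the IDs with microRNAs was given, so no probe is named, no probe could be assigned to rat, and the 18 microRNA lists (145 entries) fixed before the data were examined could not be applied. The first part of the named-gene rule fixed beforehand, the probes with the largest differences in each direction among those at 2-fold, well above background on both arrays and with separated spots, was cut from 8 to 2 in each direction because the IDs cannot be interpreted. Parts of the rule that go by microRNA name could not be applied. No probe is given under its part for probes not well above background on both arrays. The files mark no spot as a control. Each array has 11204 spots of 2674 probe IDs. The 2663 IDs printed on 4 spots were taken as the measured probes. The 11 IDs printed more often (5 on 8 spots, 6 on 36 or more) were left out of the comparison and given weight 0 in normalization. Some of the 4-spot IDs can still be controls.

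From the intensities, background was corrected with normexp (offset 50) on median spot signal and median local background, and the mean signals planned for this step were not used. Log ratios were normalized within each array by loess (limma 3.58.1 in R 4.3.3), and the sign was set to sample over reference. Outlier spots (62 on the standard array, 42 on the nonunion array) were dropped, and the spots of a probe were averaged. A probe was kept if most of its spots were well above background in the Hy3 channel on at least 1 array (2491 probes, 2410 of them on both). The difference is the log2 ratio of nonunion minus that of standard, and a fold is 2 raised to it, on a scale that the offset compresses, most for dim probes. With 1 array per group no test was possible: no p-value is given, a fixed size of 2-fold was used, and the SD or SE over spots covers technical error within an array only. The number of arrays limits the precision. Each array is a slide of its own, so slide, labelling reaction and group cannot be told apart.

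Background correction, loess and averaging over spots were tested on simulated data. A pair of arrays was drawn from the standard array's probe levels and spot noise, over 2663 probes, with 200 probes changed in the sample channel. All probes of a channel were given the same spot noise, so the rates below need not hold for these arrays. In the simulation, outlier spots were not dropped and the Hy3 filter was not applied. In this simulated comparison of nonunion against standard, 49 of 58 brighter probes with a 4-fold change came out at 2-fold or more (84.5%), and 25 of 49 dimmer ones (51%). Of probes with a 2-fold change, 14 of 38 brighter (36.8%) and 1 of 55 dimmer ones (1.8%) did. Of 2463 unchanged probes, 3 did. The same simulated arrays were also run with an offset of 10, planned as an alternative for the data but run on the simulation only after seeing the results. With it, 58 of the 58 brighter and 35 of the 49 dimmer probes with a 4-fold change (100% and 71.4%) came out at 2-fold or more. With a 2-fold change, 26 of the 38 brighter and 32 of the 55 dimmer ones (68.4% and 58.2%) did, as did 6 of the unchanged ones. For a 4-fold change of brighter probes, 2 on the log2 scale, the median size found was 1.6 with the offset of 50 and 2.146 with that of 10. For a 2-fold change of them, 1 on the log2 scale, it was 0.876 and 1.209. Sizes of brighter probes were thus too low with the offset of 50 and too high with that of 10. A cut at 2-fold misses part of the true 2-fold changes even without bias, so those rates do not measure the offset alone. The reference channel was also compared between slides after quantile normalization, as a measure of technical difference. Other offsets, normalizations, filters, the Hy3 channel alone, single spots and the authors' values were tried as alternatives. Summaries were computed in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.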

Results

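The study compared microRNAs, short RNAs that repress messenger RNAs, in a fracture that heals and in one that does not. In 12-week-old male Sprague-Dawley rats, the femoral shaft was broken over an intramedullary wire. The standard fracture was left to form a callus, the cartilage and new bone that bridge a healing break. In the nonunion model the periosteum, the membrane that supplies bone-forming cells, was also burned away over 2 mm on each side of the break, and fibrous tissue was collected instead of callus. Tissue was taken on day 14. Each group is represented by 1 array of RNA from 5 pooled animals, so there is no replicate, and every difference below is a difference between these 2 arrays.

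Most probes were dim. In the Hy3 channel, which carried the sample, the 2663 probes had a median net signal of 34.4 on the standard array and 33.3 on the nonunion array, against local backgrounds of 21 and 23. Signal well above local background was recorded for 2470 probes (92.8%) of the standard sample and 2431 (91.3%) of the nonunion sample. A group of 5 weak probe IDs, printed on 36 to 76 spots each, gave a median net Hy3 signal of 46.4 on the standard array and 47.1 on the nonunion array, above the median probe. Only 631 probes (23.7%) of the standard sample and 658 (24.7%) of the nonunion sample exceeded the 95th percentile of those spots. Saturation touched few spots, 9 and 2 in the Hy3 channel and 17 and 20 in the Hy5 channel of the standard and nonunion arrays.

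The comparison of nonunion tissue with standard callus asked which microRNAs differ between failed and normal healing. Of 2491 probes, 5 were at least 2-fold higher and 4 at least 2-fold lower on the nonunion array, 0.36% in all. At 1.5-fold the counts were 18 higher and 19 lower. The difference was below 1.2-fold either way for 91.6% of probes, and its median over probes was 0.005 on the log2 scale. The offset compresses these differences, most for dim probes. In the simulation with the offset of 50, dimmer probes with a 2-fold change had a median size of 0.461 on the log2 scale. The 91.6% therefore does not show that dim probes hardly differed between the samples. The 9 probes at 2-fold were all in the brightest 20% of the probes, and this placement depended on the processing: with Feature Extraction's processed signals 21 probes were higher and 15 lower, 17 of them in the dimmest 3 of 5 groups by brightness, and with the authors' values 21 were higher and 13 lower, 15 of them there. With median centring in place of loess, 2 probes were higher and 14 lower, and 12.5% of the changed probes were then higher against 55.6%. From the processed Hy3 signal alone, 19 were higher and 37 lower, and 33.9% were then higher.

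The files do not pair probe IDs with microRNAs, so the probes with the largest differences are given by ID. Probe 11052 was 2.76-fold higher on the nonunion array, with a range of 2.69 to 2.83 for 1 SE over spots. Its log2 ratio of sample over reference was -0.78 ± 0.05 (SD, n = 4 spots) on the standard array and 0.68 ± 0.05 on the nonunion array, and its mean net Hy3 signal was 126.0 and 398.4. Probe 5740 was 2.71-fold higher (2.66 to 2.76). Its log2 ratio was -0.73 ± 0.04 on the standard array and 0.71 ± 0.03 on the nonunion array, with net Hy3 signals of 592.6 and 1469. In the other direction, probe 4700 was 2.22-fold higher on the standard array than on the nonunion array (2.15 to 2.29), with log2 ratios of 0.64 ± 0.08 on standard and -0.51 ± 0.03 on nonunion and net Hy3 signals of 751.3 and 295.2. Probe 42865 was 2.20-fold higher on the standard array (2.16 to 2.25), with log2 ratios of 0.49 ± 0.06 on standard and -0.65 ± 0.01 on nonunion and net Hy3 signals of 246.0 and 88.9. Its nonunion signal of 88.9 lay below the 95th percentile of the spots of the weak probe IDs on that array (96.9). The standard signal of probe 11052, 126.0, was little above that percentile on the standard array (112.5). Median centring brought probe 5740 to a log2 difference of 0.98, just under 2-fold. In the Hy3 channel alone after quantile normalization, probes 4700 and 42865 differed by -0.88 and -0.96, also under 2-fold. The other 3 probes higher on the nonunion array lay between 2.18-fold and 2.53-fold, and the other 2 that were lower lay between 2.03-fold and 2.06-fold.

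**Figure D1:**
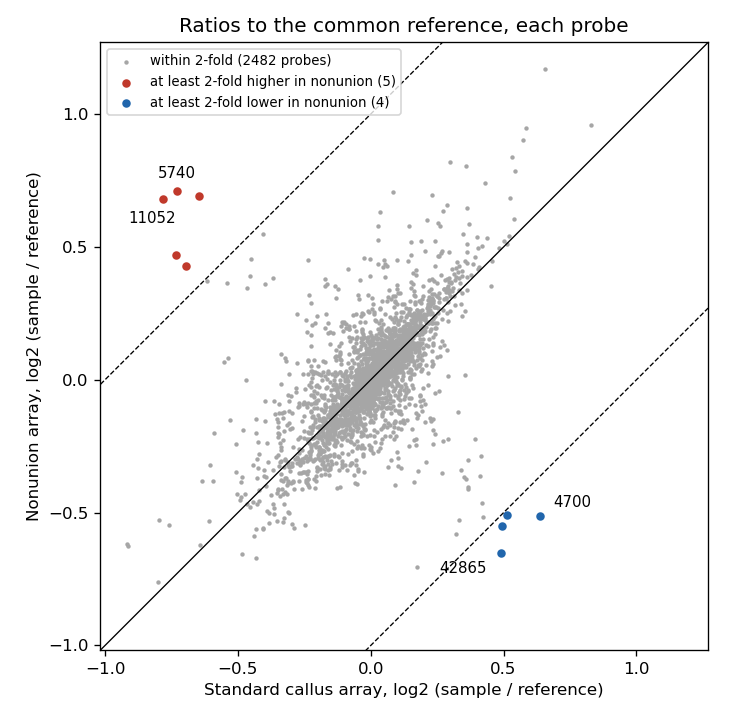
Each point is 1 of 2491 probes, with its log2 ratio of sample over reference on the standard array (x axis) and the nonunion array (y axis); the solid line marks equal ratios and the dashed lines a 2-fold difference. Most probes follow the solid line, and the 5 red and 4 blue probes at 2-fold lie on opposite sides of 0 on the 2 arrays.

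**Figure D2:**
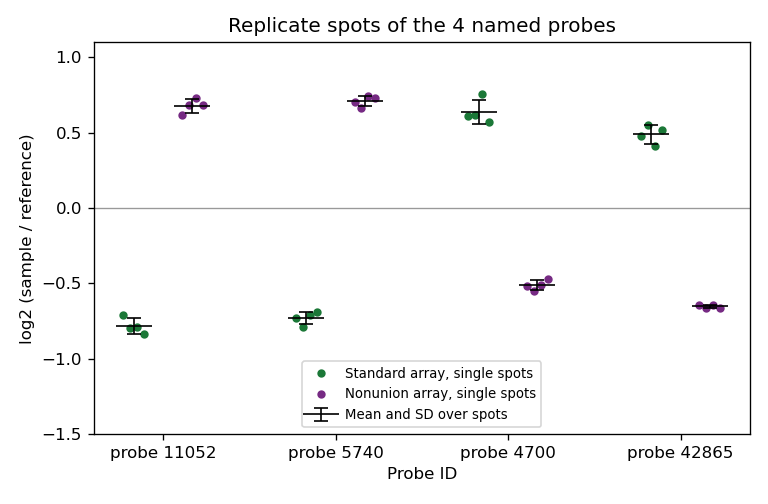
Points are the log2 ratios of sample over reference (y axis) of the single spots of probes 11052, 5740, 4700 and 42865 (x axis) on the standard (green) and nonunion (purple) arrays, and black marks are the mean and SD over 4 spots. For each probe, the spots of the arrays do not overlap.

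Each difference was set against the technical spread. The median SD over the spots of a probe was 0.057 on the standard array and 0.059 on the nonunion array, in log2 units, and in all 9 probes at 2-fold every spot of one array lay beyond every spot of the other. This was also so for the 37 probes at 1.5-fold. Over all 2491 probes, 678 (27.2%) had separated spots, 363 higher and 315 lower on the nonunion array, where chance order of 4 spots against 4 would give 2.86%. A difference of slide or labelling moves all spots of a probe together, so the excess over 2.86% does not tell tissue from slide. When 2 spots of an array were set against its other 2, 0 probes differed by 2-fold on either array. The Hy5 channel held the reference on both slides and gave a second measure of technical error, without that of labelling the Hy3 samples. After quantile normalization, 1 probe differed by 2-fold between the slides in Hy5 and 9 by 1.5-fold, against 14 and 49 in the Hy3 channel treated the same way. The SD over probes of the difference between slides was 0.127 in the Hy5 channel and 0.194 in the Hy3 channel. Spots were separated for 3.7% of probes in the Hy5 channel and 13.2% in the Hy3 channel. These values describe spots and slides, and do not include the spread between animals, which pooling removed from view.

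**Figure D3:**
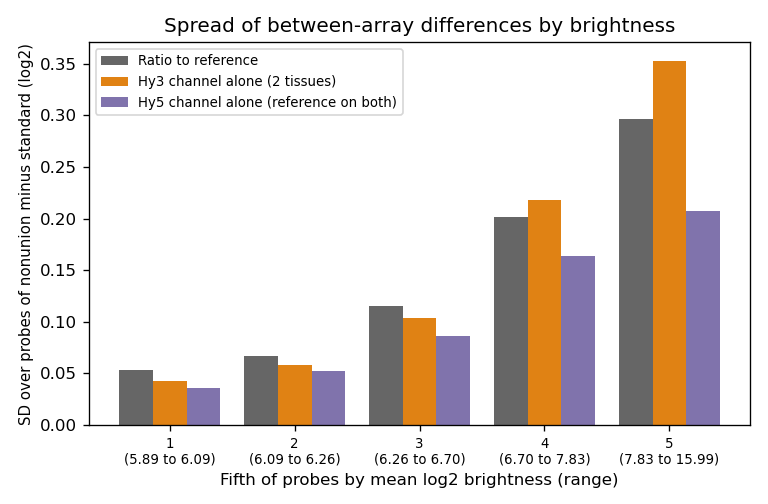
Bars give the SD over probes of the log2 difference between the nonunion and standard arrays (y axis), for the ratio to the reference, the Hy3 channel alone and the Hy5 channel alone, in 5 groups of 498 or 499 probes by mean log2 brightness (x axis). In the brightest group the SD was 0.353 in the Hy3 channel and 0.207 in the Hy5 channel, and in the dimmest 0.043 and 0.036.

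A reference mixed in equal parts from the 2 samples sets a balance: the linear ratios of both samples to it add up to 2 for each microRNA. The sum averaged 2.02 ± 0.24 (SD over 2491 probes), and in the 9 probes at 2-fold it lay between 1.96 and 2.26. Loess centres the log ratios of each array on 0, so a mean sum near 2 follows from the normalization and does not test the mix. All 9 were above the reference on one array and below it on the other. Picking probes by a 2-fold difference between ratios centred on 0 favours this, and also a sum near 2 in the 9, so neither tests the mix. Over all 2491 probes, the ratios of the arrays were positively correlated (Pearson r = 0.605, Spearman rho = 0.649, across probes, which are not independent replicates). In the brightest 20% of the probes r was 0.133, and in the dimmest 20% it was 0.874.

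The values in the authors' deposited table gave the same direction for the 4 named probes. In that table the log2 ratios were -0.97 on standard and 0.79 on nonunion for probe 11052, -0.78 and 0.76 for probe 5740, 0.75 and -0.54 for probe 4700, and 0.65 and -0.95 for probe 42865. Across the 2491 probes, the difference between the columns of the authors' deposited table and the difference from the loess-normalized ratios had a Pearson r of 0.771 and a Spearman rho of 0.805.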

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

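The probe printed 180 times, probe 13138, lay outside the comparison and was flagged because it gave a strong signal there. Its median net Hy3 signal was 21906 on the standard array and 21592 on the nonunion array, while its net Hy5 signal was 6.35 and 6.63. No microRNA or role is given for it in the files.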

How the results depend on the processing

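Of the 16 alternatives run, 2 were chosen after seeing the data. These 2 and 2 others change only which probes are included and leave the value of each kept probe as it was. Under each of the other 12, all 9 probes at 2-fold kept their direction and at least 6 of them stayed at 2-fold. The numbers at 2-fold (5 higher, 4 lower) were 21 and 15 with Feature Extraction's processed signals and 21 and 13 with the authors' values, where 17 and 15 of the changed probes lay in the dimmest 3 of 5 groups of probes by brightness. They were 11 and 6 with an offset of 10, 2 and 14 with median centring, 8 and 6 in the Hy3 channel alone after quantile normalization, 19 and 37 in the Hy3 processed signal over its 75th percentile, and 8 and 6 from spot 3 alone. The cause was not tested. The correlation of the arrays' ratios (0.605) was 0.823 with processed signals, 0.83 with the authors' values, 0.762 with an offset of 10, 0.863 with median centring, 0.715 with loess fitted on probes well above background in both channels, 0.539 and 0.542 from spot 3 and spot 4 alone, and 0.239 over the 690 probes above the weak repeated spots (chosen after seeing the data). The reference balance (2.02) was 2.19, 2.135, 2.066, 1.97 and 2.202 under the first 5 of these, and 1.994 and 2.047 from spot 2 and spot 4 alone. Of 48 values of the 4 named probes under the 12 alternatives that change values, 22 moved by less than the SD over spots, 26 by more and 0 changed sign. Filters on dim probes, the median over spots and the probes on 8 spots left the counts at 5 and 4. Limiting the probes to rat and the tests of microRNA lists were not run, because probes have no names, and with 1 array per group no replicate could be left out. In a simulation, 4-fold changes came out at 2-fold for 51% of the dimmer and 84.5% of the brighter probes with the offset of 50. With an offset of 10, a run added after seeing the data, it was 71.4% and 100%, so part of what was missed in the simulation came from the offset. The simulation gave all probes of a channel the same spot noise, so its rates need not hold for these arrays.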

Other observations

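The comparison of channels for the 2-fold probes, the test of light leaking between channels and the comparison of SDs and covariances of the ratios were chosen after the result was seen. The thresholds of the other tests were written before, and the reading of the correlation in bright probes as undecided was made after seeing it.

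The 9 probes at 2-fold between the arrays are not named in the files. Slide-to-slide noise shared by both channels cancels in the ratio by which the 9 were picked, so the channel counts do not test it. Noise of equal size in each channel but independent between them is argued against as the whole cause of the 9. The Hy3 channel gave 14 probes at 2-fold and the Hy5 channel, with the same reference on both slides, gave 1. Fewer probes were well above background in Hy5 (1319 on standard, 1596 on nonunion) than in Hy3 (2470 and 2431), so these counts are not on equal terms. The Hy5 channel also cannot show noise that arose in isolating or labelling the RNA of the Hy3 samples. The 14 are not the same set as the 9: of the 9, 6 were at 2-fold in the Hy3 channel alone and 0 in the Hy5 channel, with log2 differences of at least 0.813 in Hy3 and at most 0.432 in Hy5, whatever the sign. A few deviating spots are excluded too, since all 9 had separated spots. A difference of pool, labelling reaction or slide cannot be told apart from a difference of tissue, because there was 1 array per group. A difference between callus and fibrous tissue stays open as an untested explanation.

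The ratios of the arrays correlated positively, although a reference mixed from the 2 samples should push a changed microRNA in opposite directions. In the brightest 20% of the probes r fell to 0.133. A low value was predicted by nonspecific signal of dim probes, and not by a dye preference of each probe that is equal on both arrays. Neither is settled by it, because differences between the samples also lower r, and between the slides the Hy3 channel varied more than the Hy5 channel in these probes (SD 0.353 against 0.207). The SD of the mean of the 2 ratios was 0.169 in the brightest 20% and 0.095 in the dimmest. On the same scale, that of their difference divided by 2 was 0.148 and 0.027. The covariance was 0.00674 and 0.00827, against 0.03444 in the middle 20%. The error over spots of that mean was 0.019 and 0.027, which covers error within an array and leaves out labelling and hybridization of each array. Errors independent between the arrays raise both SDs and leave the covariance, while opposite differences of the samples from the reference lower the covariance, so neither value shows how much of the ratios was shared. A dye preference also cannot be told apart from a reference that differs from both samples alike, because both samples were labelled with Hy3 and no dye swap was analysed here.

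Both channels shifted together between slides: across 2491 probes, the Hy3 and Hy5 differences had a Pearson r of 0.56, while the ratio difference was unrelated to the Hy5 difference (r = 0.009). Hy3 light read in the Hy5 channel is excluded by probe 13138, whose Hy5 net signal was at most 0.031% of its Hy3 net signal. Differences in probe amount or hybridization from spot to spot are a candidate explanation: within an array, deviations of single spots from their probe's mean correlated between the channels with r = 0.938 on the standard array and 0.888 on the nonunion array, over the 1317 and 1574 probes well above background in both channels. If so, differences taken from the Hy3 channel alone carry an error that the ratio to the reference removes.

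The authors' deposited table holds 6 IDs with no spot in the scanner files analysed here. Their differences of nonunion minus standard in the authors' deposited table ranged from -0.66 to 0.69 on the log2 scale, and 0 of them reached 2-fold. Among the 5 probes printed on 8 spots, probe 147513 had the largest difference, 0.83 on the log2 scale, with log2 ratios of -0.44 ± 0.08 on standard and 0.39 ± 0.10 on nonunion (SD over 8 spots).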
